A study of Homo sapiens with 2 samples.

How the data were processed

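5-hydroxymethylcytosine (5hmC) is an oxidised form of 5-methylcytosine that is abundant in brain DNA. Per the labels' protocols, DNA was taken from sections of about 100 mg of frozen dorsolateral prefrontal cortex, the 5hmC-bearing fragments were chemically labelled and captured by affinity, libraries were built from 2 µg of DNA and sequenced as paired reads of 150 bases. The series holds 1050 such libraries, 1 for each participant of a pair of ageing cohorts. The labels give 1 tissue and no trait, diagnosis or other property of a library, so no comparison between participants with and without a trait was made. The libraries form 1 group, and 2 records divide them by library number, from 1 to 888 and from 879 to 1050. The records were used only as a technical batch, and the 10 libraries whose numbers lie in both ranges were left out of every comparison of records, which left 878 and 162 libraries.

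The deposited table holds 1 row for each of 197765 peaks and 1 column for each library, on a log2 scale. Per the submitters' processing notes, Trimmomatic 0.39, Bowtie2 2.3.5.1, Picard 2.21.2, MACS2 2.2.7.1, DiffBind 3.0 and edgeR were used with the genome build GRCh38. The role of each tool, the filters on reads and peaks, and the name of the normalization are not given in the sources used here. The unit was therefore worked out from the values. After the log2 was undone, every value was a whole number of reads plus an offset, multiplied by a factor of its library and divided by a width of its peak. With widths taken as whole base pairs, 100% of the values gave whole read numbers within 0.01 of a read. The offset averaged 0.50 reads and grew with library size, and the scale that fits is RPKM, reads per kb of peak and per library size. The deposited log2 values are called log2 read density below. The effective library size of each library is its reads in peaks multiplied by a scaling factor, and the geometric mean of the 1050 factors came out at 1, which also fixes the unit of the widths. The recovered reads were used for depth, for counting error and for some alternatives. The main tests of peak levels ran on the deposited log2 scale. Library pairs, reads in peaks, scaling factors and shares of reads were tested on the recovered reads, and covered share and peak width on the recovered widths.

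The peak identifiers give a chromosome code and a serial number, and positions and gene names are not given in the sources used here. The codes were read as chromosome numbers, and neighbouring peaks are those with successive serial numbers on 1 chromosome. The results planned before the data were examined on genes, gene lists, cell type markers and genomic classes (promoter, exon, intron, intergenic) needed positions and were not computed, so no gene is named and no gene list is reported. Components and the comparison of records were computed on peaks in place of genes. The other peak-level results (width, chromosome, variability and neighbours) were chosen after seeing the data. Peaks with codes 23 and 24, 8457 in all, were left out, which left 189308 autosomal peaks. The gene annotation was RefSeq on GRCh38.p14, with 19126 protein-coding genes on the 22 autosomes. It supplied the number of protein-coding genes per Mb, the share of a chromosome inside their bodies, and the chromosome's span, taken as the end of its last annotated gene. The span counts from the start of the chromosome, and stretches without assembled sequence were not subtracted.

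Each library gave 1 value per quantity, and n counts libraries, so that SDs describe the spread between participants and libraries together. Peaks were divided by width into 5 classes of nearly equal size, and a library's value for a class is the median over its peaks. Variation beyond counting was the coefficient of variation left after the Poisson part was subtracted from the variance of the recovered reads around the value set by effective library size. The robust SD is the interquartile range scaled to a normal SD. Principal components were taken of the peak by library table after each peak was centred, with the SD of a share from 100 bootstrap draws of libraries. Tests of a mean used 100000 random sign flips, and correlations and differences of a single value used 100000 permutations. All were two-sided, with Benjamini-Hochberg adjustment within a family. The smallest p such a test can give is 1e-05. The records were compared with limma 3.58.1 (R 4.3.3), a moderated test with Benjamini-Hochberg adjustment at 0.05. The other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and numba 0.67.0.

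The recovery of reads, the variation beyond counting and the test between records were tested on simulated data. Widths and reads were recovered for 100% of 60000 simulated peaks in 300 libraries. A true coefficient of variation of 0.224 was estimated at a median of 0.222 there. In a simulated comparison of records over 20000 peaks and 1040 libraries, the test called 93% of the 100 peaks changed by 0.25 log2 units and 100% of the 100 changed by 0.5, with 11 unchanged peaks called. The simulated peaks varied independently, with 1 coefficient of variation for all and the same spread in both records. The real peaks share variation across libraries and differ in spread, so these rates need not hold for them. To look for a library present more than once, the reads of all 550725 pairs of libraries were compared by chi-square over the autosomal peaks. No pair held identical values and none agreed within sampling noise. The closest pairs had 1.0178 and 1.0180 per degree of freedom, the next 1.036 and the median pair 2.43, where sampling noise alone gives 1. For the closest pair the chi-square test gave a one-sided p of 2.1e-08. The comparison bears on 1 library held in 2 columns and does not exclude 2 libraries from 1 participant. All 1050 were kept as the labels give them.

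Reads in peaks ranged from 2635620 to 23544960 per library, with a median of 7657806. The median autosomal peak and library had 18 reads, so a single value of a narrow peak carries a large counting error, while a mean over all libraries does not. Alternatives left out the lowest 25% of peaks by mean level, the libraries of either record, or 52 libraries (5%). Those 52 had the lowest correlation to the mean profile, with r from -0.012 to 0.35 against a median of 0.82. Other alternatives centred each library on its median, normalized quantiles, removed an enrichment covariate or component 1, or regressed on depth. The rest changed the offset or the scaling, left out the division by width, or thinned the reads to 4369464 per library. Thinning left out the 53 libraries below that depth (also left out once without thinning).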

Results

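The 5hmC profile of bulk dorsolateral prefrontal cortex, a frontal association area, was measured in 1050 participants with 1 library each, by chemical labelling and capture of 5hmC-bearing DNA followed by sequencing. The series title ties the study to Alzheimer's disease neuropathology. The labels carry no trait per library, so the values below describe the 5hmC landscape of this cortex and its variation between libraries, 1 per participant. Reads in peaks averaged 8187284 ± 2862807 (SD, n = 1050) per library. All levels are log2 read densities, reads per kb of peak scaled to library size (RPKM).

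5hmC peaks covered a large part of the autosomes and were most extensive on the chromosomes richest in genes. The 189308 autosomal peaks spanned 733 Mb, 25.5% of the 2874 Mb of autosomal span. On chromosome 19, which carries 24.8 protein-coding genes per Mb, peaks covered 60.3% of the span, and on chromosome 17, with 14.04 genes per Mb, 48.0%. Chromosomes 22, 16 and 20 followed with 41.4%, 36.3% and 35.9%. The lowest shares were 15.7% on chromosome 13, with 2.96 genes per Mb, and 16.7% on chromosome 4, with 4.05 genes per Mb. Unassembled stretches count as span without peaks or genes. Shares and gene densities of chromosomes with long gaps are therefore too low, and the order of chromosomes may change without them.

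Across the 22 autosomes the covered share rose with protein-coding gene density (Pearson's r = 0.92, permutation p = 1e-05, adjusted p = 1e-04; Spearman's rho = 0.89, p = 1e-05, adjusted p = 5e-05; both raw values the smallest that 100000 permutations can give). Without chromosomes 19 and 17, the farthest from the median density, r was 0.83. The adjustment covered 10 relations. The covered share also rose with the share of the chromosome inside protein-coding gene bodies (r = 0.67, p = 0.00072, adjusted p = 0.0034; rho = 0.71, p = 0.00029, adjusted p = 0.00097; r = 0.66 without the 2 farthest chromosomes). The covered share and both gene measures are divided by the same span. Unassembled stretches lower them together and can add to these relations.

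Gene-rich chromosomes tended to have wider peaks. Median peak width was 4552 bp on chromosome 22, 4292 bp on chromosome 19 and 3183 bp on chromosome 17, against 1399 bp on chromosome 4 and 1477 bp on chromosome 13. Chromosome 11, with 9.63 genes per Mb, had a median of 1834 bp, near the 1807 bp of all autosomal peaks. Median width rose with gene density (r = 0.78, permutation p = 0.0010, adjusted p = 0.0034; rho = 0.86, p = 1e-05, adjusted p = 5e-05; r = 0.62 without chromosomes 19 and 17). For the number of peaks per Mb no relation to gene density was detected (r = 0.095, permutation p = 0.65, adjusted p = 0.71; rho = 0.053, p = 0.82, adjusted p = 0.82; r = -0.18 without chromosomes 19 and 17). It rose with the share inside gene bodies (r = 0.62, permutation p = 0.0019, adjusted p = 0.0047; rho = 0.68, p = 0.00055, adjusted p = 0.0014; r = 0.50 without the 2 farthest), for which the relation of width did not pass by r (0.40, permutation p = 0.065, adjusted p = 0.093; rho = 0.51, p = 0.017, adjusted p = 0.034; r = 0.36 without the 2 farthest). The number was 68.8 per Mb on chromosome 19 and 67.2 per Mb on chromosome 4. Peaks per Mb and the share inside gene bodies are divided by the same span. Unassembled stretches lower both and can add to their relation.

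**Figure D1:**
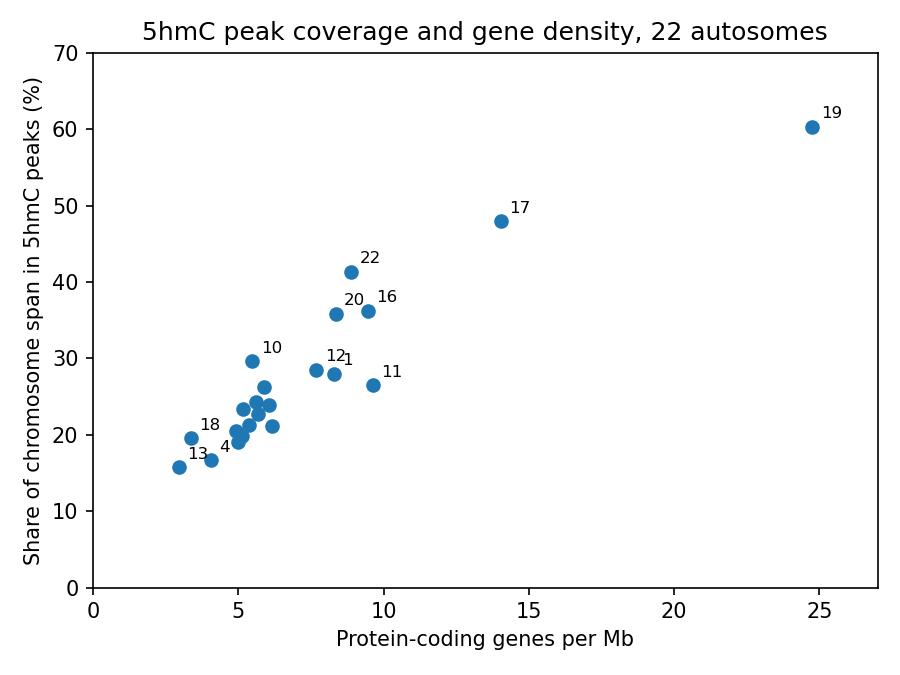
Share of each autosome's span inside 5hmC peaks (y axis, percent) against protein-coding genes per Mb (x axis), 1 point per autosome, with chromosome numbers beside the points outside the dense middle and beside chromosome 10. Chromosome 19 lies at 60.3% and chromosome 13 at 15.7%.

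Most peaks were narrow, while most reads fell in wide ones. Autosomal peaks ranged from 393 to 248831 bp, with a median of 1807 bp. The 14381 peaks of at least 10000 bp made up 7.60% of the peaks and 44.2% of the covered length, and 86 peaks reached 100000 bp. The widest, C02P101050 on chromosome 2, had a mean log2 density of -0.10 ± 0.59 (SD, n = 1050). The widest of the 5 width classes (4579 bp and above) held 62.1% ± 6.12 (SD, n = 1050) of a library's autosomal reads in peaks, and the narrowest (393 to 764 bp) held 4.99% ± 1.08.

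Read density was highest in narrow peaks. The mean over libraries was 1.11 ± 0.13 (SD, n = 1050) in the narrowest class, 0.63 ± 0.07 in the next, 0.33 ± 0.05 in the middle class (1436 to 2323 bp), 0.28 ± 0.05 in the class from 2324 to 4578 bp and 0.30 ± 0.20 in the widest. The narrow minus wide difference was 0.82 ± 0.33 (SD, n = 1050; sign-flip permutation p = 1e-05, two-sided, the smallest possible), with narrow peaks the denser in 1007 libraries and wide peaks in 43. It was 0.87 ± 0.28 in the 878 libraries of record 1 and 0.57 ± 0.41 in the 162 of record 2, each with a sign-flip permutation p of 1e-05. Widths and densities come from the same reads, and without the division by width the wide peaks held more reads (log2 difference -3.00 ± 0.35).

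**Figure D2:**
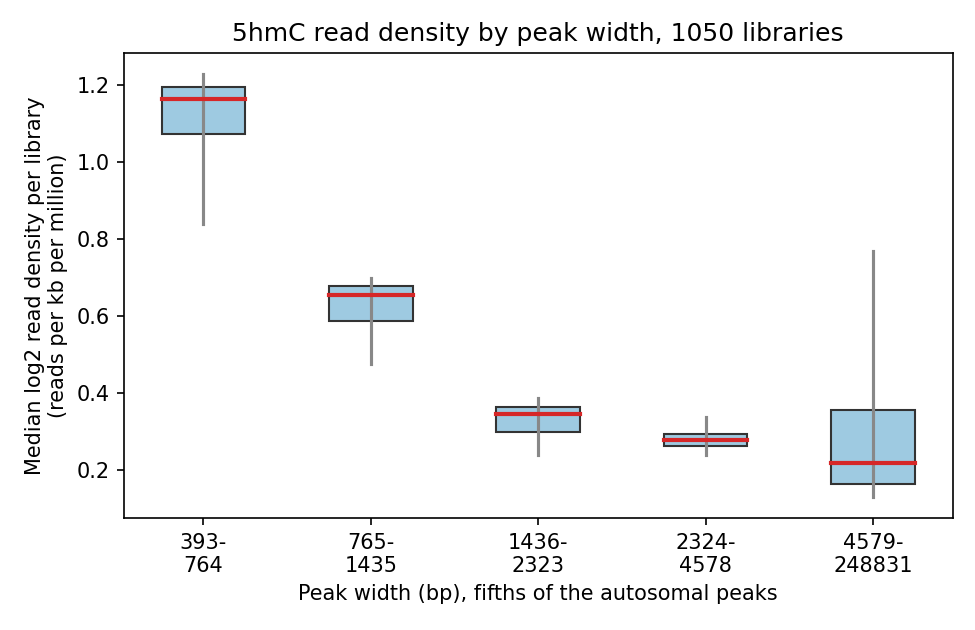
Median log2 read density per library (y axis, RPKM) in the 5 width classes of the autosomal peaks (x axis, bp), over 1050 libraries. Red lines are medians over libraries, boxes the range from percentile 25 to percentile 75 and grey lines the range from percentile 5 to percentile 95. The narrowest class has the highest density and the widest class the largest spread between libraries.

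Chromosome 19 also had the highest mean density over its peaks, 0.63 ± 0.16 (SD, n = 1050), and took 6.56% ± 0.676 of the autosomal reads in peaks with 4.82% of the covered length. It was the densest autosome in 715 of 1050 libraries, and chromosome 4, whose mean was 0.50 ± 0.05, in 305. The lowest means were 0.37 ± 0.10 on chromosome 20 and 0.38 ± 0.21 on chromosome 22. Chromosome 22 was the lowest in 665 libraries and the highest in 29. The relation of mean density to gene density rested on chromosomes 19 and 17 (r = 0.60, permutation p = 0.024, adjusted p = 0.044; rho = 0.069, p = 0.76, adjusted p = 0.82), and r was -0.34 (permutation p = 0.15) without them. With the share inside gene bodies, r was 0.47 (permutation p = 0.027, adjusted p = 0.044; rho = 0.30, p = 0.17, adjusted p = 0.24) and 0.47 without the 2 farthest chromosomes. Among single peaks, C17P072452 on chromosome 17 (1387 bp) and C11P030869 on chromosome 11 (1023 bp) had the highest means, 2.53 ± 0.38 and 2.45 ± 0.43 (SD, n = 1050). The lowest were C19P080230 on chromosome 19 (3427 bp) at -3.09 ± 2.202 and C08P181027 on chromosome 8 (2408 bp) at -2.88 ± 1.87, each with a median of 2 reads per library.

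Variation between libraries, which holds participants and handling together, was small in the median peak once counting error was set aside. The median coefficient of variation beyond counting was 12.5%, with 5.85% at percentile 5 over peaks and 90.0% at percentile 95, and 1380 peaks had none. In the median peak 79.3% of the variance came from counting. The median coefficient was 12.24%, 11.96%, 11.98% and 12.02% from the narrowest class upwards and 22.999% in the widest class, where counting made up 23.01% of the variance. The smallest SDs over libraries, counting error included, were those of C16P065359 on chromosome 16 (39515 bp, SD 0.09 around a mean of 1.07) and C03P112994 on chromosome 3 (58034 bp, SD 0.09 around 1.04), both wide, with little counting error at medians of 669 and 955 reads.

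A small set of peaks varied far more. The most variable 1% by robust SD, 1893 peaks, had a median robust SD of 1.76 against 0.41 over all peaks, a median width of 8672 bp and a median mean density of -0.55. They made up 2.76% of the peaks of chromosome 22, 1.97% of chromosome 16 and 1.96% of chromosome 20, against 0.493% of chromosome 3 and 0.532% of chromosome 4. They lay next to one another in the order of peaks 423 times, where 18.9 pairs are due by chance. When the 1% was chosen in each record alone, 685 peaks were shared, where 18.9 are due for independent lists. Both chance values take all peaks as equally likely, and do not allow for width, level or variation common to a whole library. Robust SDs include counting error, which depends on width and level, and their Spearman's rho between records (0.81 across peaks) holds that part too. For the variance beyond counting the rho between records was 0.62 across peaks, which are not independent replicates. It was 0.11 within the narrowest class and 0.93 within the widest. The share of most variable peaks rose with gene density by rank (rho = 0.50, permutation p = 0.020, adjusted p = 0.034) but not by Pearson's r (0.29, p = 0.16, adjusted p = 0.20; 0.63 without chromosomes 19 and 17).

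Libraries differed along 1 leading axis, on which narrow and wide peaks moved apart. Component 1 held 27.7% ± 0.873 (bootstrap SD) of the variance between libraries, with 16.2% without the lowest 25% of peaks by mean level and 42.1% with libraries scaled to total reads in peaks. Components 2 to 4 held 3.55%, 2.63% and 2.06%. In the direction in which narrow peaks were the denser, 97.3% of the narrowest peaks correlated positively with it (median r = 0.25) and 26.98% of the widest (median r = -0.50). The wide peaks C18P080196 on chromosome 18 (50590 bp) and C12P045085 on chromosome 12 (78687 bp) both correlated with it at r = -0.99. The opposite signs belong to the deposited scaling. With libraries scaled to total reads in peaks, 62.0% of the widest peaks also correlated positively with component 1 (median r = 0.55, against 0.60 in the narrowest), and its r with the narrow minus wide difference was 0.90. The widest class took from 56.0% to 92.5% of a library's autosomal reads in peaks.

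Over the 1050 libraries component 1 followed the narrow minus wide difference (r = 0.93, rho = 0.97; r = 0.93 without the 2 farthest libraries; 0.94 in record 1 and 0.89 in record 2) and the library's scaling factor (r = 0.98, rho = 0.99; 0.98 without the 2 farthest; 0.98 and 0.98 within records). It ran against the mean level of the most variable 1% of peaks (r = -0.97, rho = -0.99; -0.97 without the 2 farthest; -0.96 and -0.97 within records). It also ran against the difference between the 5 autosomes densest in genes (19, 17, 11, 16 and 22) and the 5 sparsest (13, 18, 4, 8 and 5), with r = -0.97 and rho = -0.98 (-0.97 without the 2 farthest; -0.97 and -0.97 within records). These quantities share the same values, so their relations describe the axis and are not independent of it. Depth was related to component 1 in the pooled libraries (r = -0.46, rho = -0.47; -0.46 without the 2 farthest) and in record 1 (-0.46), and not in record 2 (0.04). Each pooled relation had a permutation p of 1e-05, the smallest possible, and adjusted values of 1e-05 for r and 1.2e-05 for rho over 6 relations. The levels of the gene-dense and gene-sparse autosomes, the sixth relation, had r = -0.31 and rho = -0.12 (p = 1e-05 and 0.00019, adjusted p = 1e-05 and 0.00019; r = -0.27 without the 2 farthest; -0.13 and -0.52 within records). Its sign depends on the processing, since r was 0.97 with libraries scaled to total reads in peaks and 0.51 with component 1 removed. Its size does too, with r = -0.98 under quantile normalization, -0.11 with an offset of 2 reads and -0.14 without the 52 libraries least like the mean profile.

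**Figure D3:**
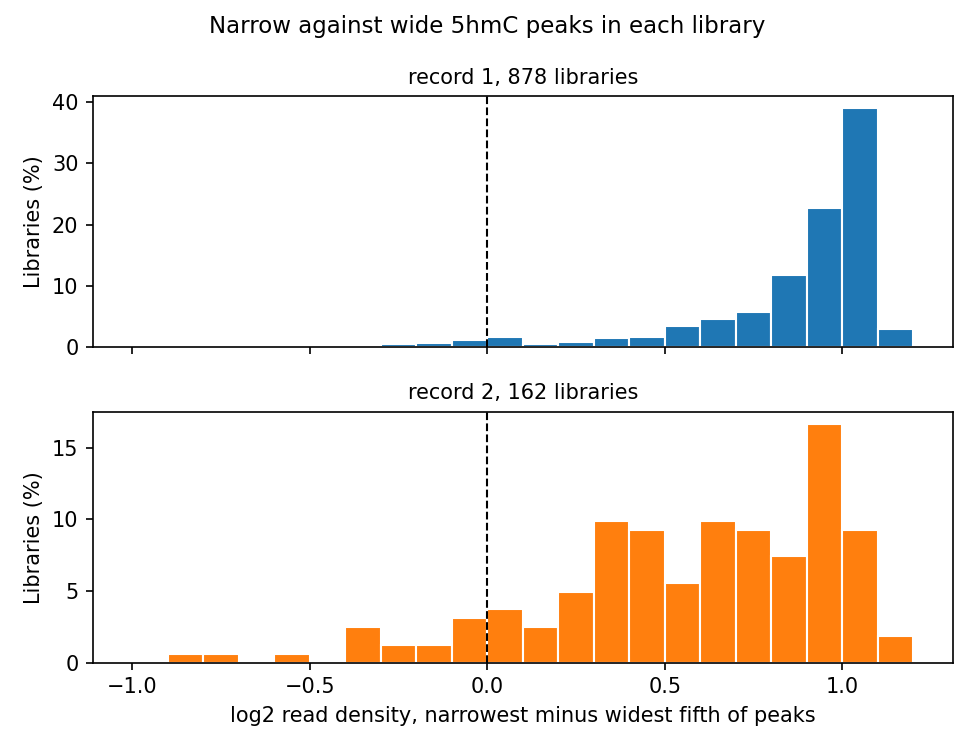
Distribution over libraries of the log2 read density of the narrowest minus the widest class of peaks (x axis, bins of 0.1 log2 units), as percent of the libraries of each record (y axes, which differ in scale), with 878 libraries in record 1 and 162 in record 2. The dashed line marks 0. Record 2 has a mean of 0.57 and record 1 of 0.87, and both have a tail below 0.

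Neighbouring peaks varied together between libraries. The median r over 1050 libraries was 0.070 for 189286 pairs of successive peaks, against 0.012 for 47150 random pairs on different chromosomes. With libraries scaled to total reads in peaks these medians were 0.41 and 0.37, a difference of 0.040. As deposited, the median was 0.043 at 10 steps, 0.025 at 100 steps and 0.017 at 1000 steps. Pairs with r above 0.5 made up 6.76% of successive pairs and 1.45% of pairs on different chromosomes. The median for successive peaks lay above that for different chromosomes on 22 of 22 autosomes (difference 0.058; sign-flip permutation p over autosomes 1e-05, two-sided, the smallest of 100000 draws). The autosomes share the same libraries and a common median for different chromosomes. They are not independent, so this p does not measure the spread between participants. It ranged from 0.060 on chromosome 13 to 0.17 on chromosome 19.

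**Figure D4:**
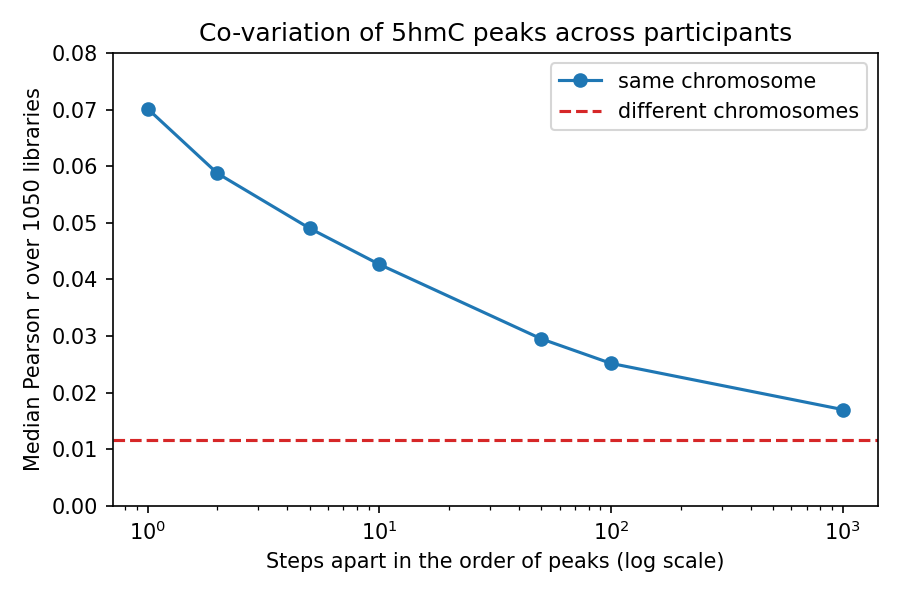
Median Pearson r over 1050 libraries (y axis) between autosomal peaks that lie 1 to 1000 steps apart in the order of peaks on a chromosome (x axis, log scale). The dashed line gives random pairs on different chromosomes. The median falls from 0.070 at 1 step to 0.017 at 1000 steps and stays above the line at 0.012.

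The libraries of the 2 records differed in most peaks, as a technical batch can. With limma and Benjamini-Hochberg adjustment, 138769 of 189308 autosomal peaks (73.3%) passed an adjusted p of 0.05, with 66042 higher and 72727 lower in record 2. The median size over all peaks was 0.15 on the log2 scale, and 23469 of those called differed by more than 0.5. In the widest class 25750 peaks were higher and 7012 lower in record 2. In the narrowest class 5167 were higher and 19836 lower. C19P080230 on chromosome 19 was higher in record 2 by 3.38 ± 0.16 (SE; limma adjusted p = 5.2e-85), with means of -0.26 ± 2.302 (SD, n = 162) and -3.64 ± 1.72 (SD, n = 878). C04P132580 on chromosome 4 was higher by 3.10 ± 0.14 (SE; limma adjusted p = 8.7e-90). Both peaks had few reads, with medians of 2 and 5 per library, so the size of these differences depends in part on the offset. C12P044960 on chromosome 12 (-2.14 ± 0.05, SE; limma adjusted p = 1.1e-234) and C01P010795 on chromosome 1 (-2.12 ± 0.06, SE; limma adjusted p = 6.6e-194) were lower in record 2. Their SDs were 0.93 and 1.15 in record 2, against 0.47 and 0.52 in record 1. The test pools the variance of both records, so with the smaller record the more variable, these SEs and p-values are too small. Other calls may share this limit.

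The split of those calls depends on the scaling and on the libraries. Without the 52 libraries least like the mean profile 75852 peaks were higher and 62802 lower in record 2, and with component 1 removed 67507 and 58691. With libraries scaled to total reads in peaks, the median difference over all peaks moved from -0.01 to -0.34, and 16313 peaks were higher and 161914 lower in record 2. Libraries of record 2 held more reads in peaks (10690383 ± 2579787, n = 162, against 7689877 ± 2648108, SD, n = 878) and more of them in the widest class (68.0% ± 8.34 against 61.0% ± 4.83). Both differences had a permutation p and an adjusted p of 1e-05 over 4 comparisons, the smallest possible.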

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

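Alternatives for component 1 and the records were planned before the data were examined, except regression on depth, removal of component 1, the offset of 2 reads, scaling to total reads, thinning and leaving out the shallowest libraries. All other alternatives were chosen after seeing the data. Of 72 alternative values, 54 kept the direction and side of the threshold, or stayed within the spread. These included every alternative run for the excess of neighbour r over r between chromosomes (0.032 to 0.084), the relation of covered share to gene density (r from 0.62 to 0.97), the rho of robust SDs between records (0.73 to 0.87) and the number of peaks that differ between records (99769 to 178227). For the records this refers to the number of calls only. The majority direction of the calls turned without the 52 libraries least like the mean profile and with component 1 removed. With component 1 removed, many of the peaks called were also different ones. The narrow minus wide difference stayed between 0.53 and 0.99 except without the division by width, where it was -3.00, because a wide peak holds more reads. The share of component 1 moved from 27.7% to 16.2% without the lowest 25% of peaks by mean level, 23.2% without the 52 libraries least like the mean profile, 22.7% with quantile normalization, 23.5% with regression on depth, 20.5% with reads thinned to 1 depth without the 53 libraries below it, 29.0% without those libraries and no thinning, 31.5% with an offset of 2 reads and 42.1% with scaling to total reads. Leaving out the libraries of 1 record gave 23.4% to 34.6%. The median coefficient of variation beyond counting moved from 12.5% to 11.3% without those peaks, 10.4% without the 52 libraries and 10.8% to 14.1% without either record. The correlation between gene-dense and gene-sparse autosomes turned from -0.31 to 0.030 with the enrichment covariate, 0.51 without component 1 and 0.97 with total scaling. The cause of these shifts was not tested. Depth limits single values of narrow peaks, where counting made up 88.2% of the variance. Alternatives on genes, promoters and gene lists, the GC slope and the pseudocount planned for linear values were not run. No paired analysis was possible because the libraries form 1 group.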

Other observations

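The tests in this part were chosen after the patterns had been seen, except that fits without the libraries of either record were planned. The labels give no trait or cell composition per library, so no biological explanation was tested.

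The mean log2 density of the most variable 1% of peaks ran from -2.69 at percentile 5 over libraries to 1.66 at percentile 95, and they took from 0.492% to 22.98% of a library's autosomal reads in peaks.

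The axis that, with the deposited scaling, set narrow against wide peaks was weighed against 3 technical explanations. Loss of enrichment towards exactly even coverage would bring wide and narrow peaks to the same density and no further. The narrow minus wide difference was under -0.1 in 28 of 1050 libraries, so exactly even coverage cannot be the whole account. Unenriched coverage need not be even, and where it favours wide peaks it could also give values under 0. Loss of enrichment towards such coverage was not tested and stays open. Depth may hold part of the axis, since the pooled component 1 had r = -0.46 with log2 reads in peaks over all libraries and within record 1 (n = 878). Thinning 997 libraries to 1 depth gave a share of 20.5%, against 29.0% before thinning. That fall cannot decide on depth, because thinning also adds counting error to every value, which lowers the share. Depth is not the whole account, since the r of the pooled component 1 with it was 0.037 within record 2 (n = 162). There a component 1 fitted to record 2 alone held 35.1% of the variance and had r = 0.10 with depth. A difference between records is not the whole account, since component 1 held 23.4% or more with the libraries of either record left out. It may hold part of the axis. The narrow minus wide difference was 0.87 in record 1 and 0.57 in record 2 (permutation p = 1e-05). A bias towards GC-rich DNA in capture or amplification and a difference in cell composition may both favour wide peaks of gene-dense chromosomes and stay open, as neither could be tested without positions or labels.

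The difference between the 2 records could come from chance, depth or the main axis. Of 100 splits of the 1040 libraries into groups of 878 and 162, the real one included, 1 gave as many peaks (138769, with 2 as the highest other), so chance can be excluded. With reads thinned to 1 depth, in the libraries deep enough, 128810 peaks were called, against 139348 in those libraries before thinning, so depth is not the whole account. With component 1 removed 126198 were called, so it is not the whole account either, but the calls changed: 94387 were among those called before, near the 92507 expected of independent calls, and 81474 of these kept their direction. Other differences in handling or in the participants of each record cannot be separated and stay open.

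The correlation of neighbouring peaks may come from the main axis, from neighbours that are alike or from fragments that span 2 peaks. With component 1 removed, the excess of successive peaks over pairs on different chromosomes was 0.032, against 0.058 before, and it stayed above 0 on 22 of 22 autosomes. Over pairs in which a peak of like width and level on another chromosome took the neighbour's place, the excess of neighbours was 0.038. Peaks 10 steps apart, with 9 peaks between them, kept an excess of 0.031, above 0 on 22 of 22 autosomes, so none of the 3 alone is the whole account. Sequence differences between participants were not tested.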
